A study of Gallus gallus and Anas platyrhynchos and Coturnix japonica with 43 samples.

How the data were processed

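The study hybridised 43 spotted chicken cDNA arrays, each with the RNA of 1 tissue sample labelled with Cy3 and a common chicken reference pool labelled with Cy5, per the labels. The reference held liver, fat, breast muscle and hypothalamus RNA, and the labelled reference was pooled anew for each hybridisation set. No array had its dyes exchanged, so dye and sample cannot be separated, but an effect of dye common to all arrays drops out of every difference between groups. Per the labels 25 micrograms of total RNA were labelled per sample. Chicken liver, muscle and fat came from broiler cockerels at 6 weeks and chicken hypothalamus from lean line birds at 9 weeks, and muscle and fat RNA were extracted by another method than liver and hypothalamus RNA. Age and sex of the other birds are not given in the sources used here.

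The deposited values are read as linear ratios of the channels, 1 ratio per spot and array, since all lie above 0 and their medians lie near 1. Scanner, image software, background correction, normalization and which channel is the numerator are not given in the sources used here. No spot intensities are given, so signal over background is unknown, and the number of arrays limits the precision. The values were read as sample over reference, which is likely by a rule set beforehand: the median of plasma proteins lay above 0 in chicken liver, that of contractile apparatus genes in muscle and that of neuronal and synaptic genes in hypothalamus. The lowest correlation between any pair of arrays was -0.398, between chicken hypothalamus replicate 1 and chicken liver replicate 1; 11 of 903 pairs lay under -0.3 and 0 of these were within a tissue, so no array was turned round, as tissues can oppose each other and the dyes are stated. Quail hypothalamus replicate 3 is called replicate 19 in its description, and its title was followed.

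Each array had 19200 spots in 48 print blocks and 0 empty cells, so the planned share of probes with a value and the filter for probes with a value on all arrays did not apply. Array medians of the ratio ran from 0.535 to 1.83. Values were put on the log2 scale, each array was centred on its median, and spots of the same clone were averaged, which left 18547 probes. Of the spots 10601 carried 1 gene symbol, 0 carried several and 8599 were unnamed here; of the named ones 10455 matched the current chicken gene table and 146 did not. Probes that name a gene were averaged to 6428 genes for named genes and for gene lists. Within groups the median correlation of arrays was 0.300 over 57 pairs, from -0.169 to 0.632, and the SD over probes per array ran from 0.500 to 1.19. Its median was 0.776. On an array, the 94 spots listed under 1 clone had a median SD of 0.79, and 29 spots of another clone 0.608. Repeat spots of a clone thus scattered nearly as widely as different probes, which limits what a probe on a single spot can show. Differences between print blocks held 2.44% to 37.7% of the variance of an array.

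Groups were the 12 combinations of species and tissue in the labels. Limma 3.58.1 in R 4.3.3 fitted 12 group means to all 43 arrays, with eBayes and Benjamini-Hochberg adjustment over the probes of each of 19 contrasts, and a probe or gene was called at an adjusted p under 0.05; every called probe in every contrast also had a log2 difference of at least 1, a fold of 2, either way. Each tissue of chicken was compared with the mean of the other 3, liver with hypothalamus within a species, each other species with chicken within a tissue, and the liver minus hypothalamus difference of turkey, quail and duck with that of chicken. Contrasts against chicken share the same chicken arrays. Gene lists were tested with limma's cameraPR on the genes, with a preset correlation of 0.01 and with a correlation estimated from residuals, adjusted over all lists and contrasts; random lists of the same size numbered 10000. The lists were plasma proteins, hepatic amino acid, bile acid and xenobiotic metabolism, lipogenesis, cholesterol synthesis, fatty acid oxidation and ketogenesis, egg yolk precursors, acute phase, neuronal and synaptic, hypothalamic neuropeptides and regulators, glia and myelin, contractile apparatus, glycolysis and glycogen, adipocyte, connective tissue and extracellular matrix, erythrocyte, leukocyte, endothelial, ribosomal proteins, oxidative phosphorylation, proteasome, circadian clock, and heat shock and immediate early. Lists with fewer than 5 measured genes were not tested; 7 genes of the plasma protein list and 7 of the acute phase list are held by another list, as are 3 of adipocyte, 2 of fatty acid oxidation and 1 each of lipogenesis, erythrocyte and endothelial. The SD over probes per array was compared with exact permutation tests in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3; plots were drawn with matplotlib 3.10.9.

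Named genes followed a rule: per contrast, among called genes whose groups did not overlap (for the differences of differences, all called genes), the 10 with the largest difference in each direction, and up to 4 called members of each list. Genes named outside this rule are marked as chosen after their values were seen. Replicate numbers were checked for pairing by the correlation of residuals of same-numbered arrays of different groups: the mean was 0.0405, against -0.0140 for other numbers, 11 of 43 arrays were closest on average to their own number, and every pair exceeded 0.1 in the turkey liver and hypothalamus contrast alone, so no block was used and a fit with replicate as a block was an alternative. Groups, contrasts, tests, lists, the naming rule and most other settings were set before the data were examined. That plan named values without centring as the choice and median centring as the alternative; these roles were exchanged after the array medians were seen and after fits under several scalings had been looked at together. Averaging the spots of a clone, leaving out 3 arrays in doubt, centring print blocks and a residual component as a covariate were added after seeing the data.

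The fit was tested on simulated data with 200 changed probes per contrast in 5 simulations and independent noise. Over the contrasts it recovered 0% to 16.0% of log2 changes of 1, 1.60% to 58.0% of 1.5, 8.40% to 91.2% of 2 and 53.2% to 100% of 3, and at most 7.87% of calls were false. With whole residual arrays reshuffled among the groups, so that nothing changed but the arrays kept their shared structure, 0 to 5 of 100 draws per contrast gave any call, and the largest such count was 5551, for quail liver against chicken liver. The first component of the residuals held 37.3% of the variance within groups and the next 6.66%, so arrays of a group differed along a common axis. In every group of the other species replicate 1 scored above replicate 3 on it, as in quail hypothalamus (0.256 and -0.272). Chicken hypothalamus had this order too (0.165 and -0.237), while chicken muscle, fat and liver had the reverse. The labels do not give the source of that axis.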

Results

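The arrays carried RNA of 4 chicken tissues (liver, hypothalamus, breast muscle and abdominal fat, 4 arrays each) and of 5 other birds. Liver was measured in White turkey, Japanese quail and duck (4 arrays each) and in American kestrel and Tree sparrow (3 each), and hypothalamus in White turkey, Japanese quail and duck (3 each); turkey, quail, kestrel and sparrow stand for these birds below. Every spot is a chicken cDNA clone, so the comparisons ask how an array built for chicken reads tissue differences in other birds. All values below are log2 ratios to a pool of chicken tissues, whose labelled cDNA was pooled anew for each set of hybridisations, likely sample over reference, with each array centred on its median, and differences are given with their standard error (SE). The number of arrays limits the precision, and p-values measure the spread between these samples, since the labels do not say that each array came from a separate animal. A probe or gene was called at an adjusted p under the threshold of 0.05 in limma. The adjusted p of a list is that with the preset correlation unless an estimated correlation is named. Lists past the threshold that are given with the preset value alone also passed with an estimated correlation. Their adjusted p was then mostly far larger, up to 0.036. No genome position is given for the clones.

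Before the comparisons, marker genes were read on each array against its label, and 3 arrays that stood apart from their groups were taken as in doubt. On chicken muscle replicate 4 the median of the contractile apparatus list was -0.41, against 0.27 to 0.66 on the other 3 muscle arrays, and that of the glycolysis and glycogen list was -0.87, against 0.80 to 0.88. The fast troponin TNNT3 was at -2.05 and the myosin light chain MYL1 at -2.36 on that array. On sparrow liver replicate 1 the contractile apparatus list was at 0.41, against -1.01 and -0.53 on the other sparrow livers, TNNT3 was at 1.58, MYL1 at 1.97 and the blood protein ALB at -2.99. The troponin TNNC2 went the other way there, at -0.39, against 1.30 to 1.72 on the other sparrow livers. On duck hypothalamus replicate 3 the neuronal and synaptic list was at -0.69, against -0.15 and 0.19 on the other duck hypothalami, and the myelin protein MBP was at -2.05. The neuronal gene STMN3, at -0.40, lay within the other duck hypothalami, at -1.04 to -0.19. All 3 arrays stayed in the values below under their labels, and counts without them are given beside. Other arrays stood apart on the glia and myelin list and were not among these 3. Quail liver replicate 2 was at 0.515, against -0.789 to -0.0362 on the other quail livers. Chicken fat replicate 3 was at 0.454, against -0.646 to -0.416 on the other fat arrays. Quail hypothalamus replicate 3 was at -0.596, against 0.499 and -0.133 on the other quail hypothalami. Its neuronal and synaptic list was low too, at -0.194, against 0.483 and 0.199. Turkey hypothalamus replicate 3 was at -0.416 on the glia and myelin list, against 0.455 and 0.276.

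Chicken liver differed from the mean of the other 3 chicken tissues by its secreted proteins and its metabolic enzymes. ALB, the main blood protein, was at 0.82 ± 0.27 (SD, n = 4) in liver and at -2.49 ± 0.69 in hypothalamus, -2.28 ± 0.72 in muscle and -2.04 ± 0.57 in fat, a difference of 3.09 (SE 0.34, adjusted p = 6.4e-08). The largest difference was that of HSD11B1B, a steroid dehydrogenase, at 3.91 (SE 0.45, adjusted p = 1.2e-07), followed by the serine synthesis enzyme PSPH at 3.61, the fatty acid binding protein LBFABP at 3.34, the iron reductase STEAP3 at 3.23 and complement C3 at 3.17. The enzymes of alcohol and tyrosine breakdown ADH6 (2.69), HPD (2.52) and ADH1C (2.16) were higher too, as were EHHADH (1.64) and ACAA2 (1.17) of fatty acid oxidation. PTPRN, a protein of secretory granules, was lower by -1.39 (SE 0.36, adjusted p = 0.026), and the matrix proteins COL1A2 (-1.67) and SPARC (-1.66), the muscle proteins XIRP1 (-1.86) and FABP3 (-1.81) and the hexokinase HK1 (-1.0) were lower as well. Of 46 plasma proteins 24 were called higher and 0 lower over all genes, and 32 higher adjusted over the list alone; the list's median difference was 1.31 (adjusted p = 1.2e-67). FGA, FGB and C3 are held by the acute phase list too, of which 5 of 12 members were higher (median 0.79, adjusted p = 5e-18), 6 adjusted over the list alone. In the list of hepatic amino acid, bile acid and xenobiotic metabolism 8 of 35 were higher, and 12 adjusted over the list alone (median 0.48, adjusted p = 6.3e-12). The connective tissue and extracellular matrix list was lower (median -0.28, adjusted p = 2.3e-05, or 0.036 with an estimated correlation), with 2 of 55 called lower and 4 adjusted over the list alone. Calls of 5 lists were lost: lipogenesis (median 0.41, 1 of 17 called higher) had an adjusted p = 0.37 with an estimated correlation, contractile apparatus (-0.24) an adjusted p = 0.3 with an estimated correlation, glycolysis and glycogen (-0.48) an adjusted p = 0.63 with an estimated correlation, neuronal and synaptic (-0.21) an adjusted p = 0.7 with an estimated correlation, and glia and myelin (-0.24) an adjusted p = 0.73 with an estimated correlation. Without the 3 arrays the contractile apparatus list (median -0.22, 4 of 43 lower) and the glycolysis and glycogen list (-0.67, 3 of 22 lower) passed, at an adjusted p of 0.00029 and 0.043 with an estimated correlation. In all, 317 of 18547 probes were called, 299 higher and 18 lower, and 128 of 6428 genes; 344 probes were called without the 3 arrays. The groups did not overlap for 98 genes (1.52%, against 0.11% by chance).

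Chicken hypothalamus stood apart by neuronal genes. STMN3, a neuronal regulator of microtubules, was at 1.12 ± 0.37 (SD, n = 4) in hypothalamus and between -1.64 and -1.43 in the other tissues, a difference of 2.65 (SE 0.37, adjusted p = 9.3e-05). The synuclein SNCB was higher by 2.47 (SE 0.37, adjusted p = 0.00022), the myelin proteins CNP and MBP by 1.98 and 1.88, the brain creatine kinase CKB by 1.93, PTPRN by 1.85, the neuronal enolase ENO2 by 1.8 and the astrocyte filament GFAP by 1.49. Less well described genes among the largest differences were METTL15P1 (2.11), CCDC93 (1.8) and TMEM209 (1.69); TMEM209 had an adjusted p of 0.06 without the 3 arrays. The neuronal and synaptic list had 9 of 52 members called higher and 0 lower, and 26 higher adjusted over the list alone (median 0.74, adjusted p = 3e-23). Of the glia and myelin list 3 of 22 were higher, 6 adjusted over the list alone, and its median was 0.78 (adjusted p = 3.8e-10), with an adjusted p = 0.1 with an estimated correlation. The adipocyte list was lower with no member called (median -0.25, adjusted p = 0.0015). Plasma proteins (median -0.26) were lower with an adjusted p = 0.3 with an estimated correlation, connective tissue and extracellular matrix (-0.19) with an adjusted p = 0.079 with an estimated correlation, contractile apparatus (-0.36) with an adjusted p = 0.2 with an estimated correlation and acute phase (-0.21) with an adjusted p = 0.45 with an estimated correlation. Without the 3 arrays the contractile apparatus list (median -0.42, 4 of 43 lower) passed, at an adjusted p of 9.3e-05 with an estimated correlation. Called probes numbered 84, of which 75 were higher and 9 lower, and 93 without the 3 arrays; among the lower ones, named here after their values were seen, were clones of GPR183, GPX3, COL3A1, PSPH and ALB. The count was 43 with arrays not centred, 247 with equal median absolute deviation and 260 with quantile normalisation, and 34, 30 and 37 without hypothalamus replicates 1, 2 and 4. No overlap was seen for 40 genes (0.622%, against 0.11% by chance). The hypothalami came from a lean line at 9 weeks of age and the other chicken tissues from broilers at 6 weeks, so line and age go with this tissue.

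Chicken muscle differed by contractile proteins and by glycolytic enzymes, with large spread from replicate 4. MYL1 was at 0.64 ± 2.01 (SD, n = 4) in muscle and at -2.24 ± 0.77 in liver, a difference over the other tissues of 2.93 (SE 0.55, adjusted p = 0.0069) that was 3.93 (SE 0.40, adjusted p = 1.6e-08) without the 3 arrays. The fast myosins MYH1B and MYH1E were higher by 2.84 and 2.77, the Z-disc protein ACTN2 by 2.73 and skeletal actin ACTA1 by 1.82 (SE 0.31, adjusted p = 0.0035). Among enzymes of energy supply GPD1 was higher by 3.01, the adenylate kinase AK1 by 2.83, LDHA by 2.29 and PGAM1 by 1.97. PGRMC1, a haem-binding membrane protein measured by 5 clones, was lower by -1.03 (SE 0.21, adjusted p = 0.0086), and the prostaglandin synthase PTGDS by -1.85. THRSP, a regulator of lipid synthesis, was lower by -1.24, but its clones differed in sign, at -2.53 and 0.06. Of the contractile apparatus list 11 of 43 members were called higher and 0 lower, and 15 higher adjusted over the list alone (median 0.50, adjusted p = 1.5e-20). The glycolysis and glycogen list had 9 of 22 called higher, 14 higher and 1 lower adjusted over the list alone (median 1.24, adjusted p = 9.1e-21). Calls with the preset correlation were lost for lists of the other tissues: plasma proteins (median -0.51) had an adjusted p = 0.099 with an estimated correlation, lipogenesis (-0.41) an adjusted p = 0.066 with an estimated correlation, glia and myelin (-0.49) an adjusted p = 0.47 with an estimated correlation, and acute phase (-0.50) an adjusted p = 0.27 with an estimated correlation. Likewise neuronal and synaptic genes (-0.28) had an adjusted p = 0.67 with an estimated correlation, adipocyte genes (-0.22) an adjusted p = 0.051 with an estimated correlation, and leukocyte genes (-0.25) an adjusted p = 0.52 with an estimated correlation. The count was 80 probes, 67 higher and 13 lower, 195 without the 3 arrays and 175 with quantile normalisation. It was 0, 0 and 1 without muscle replicates 1, 2 and 3, and 177 without replicate 4. Of all genes 9 showed no overlap (0.14%, against 0.11% by chance).

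Chicken fat differed by adipocyte and matrix genes. FABP4, the fatty acid binding protein of adipocytes, was at 1.07 ± 0.82 (SD, n = 4) in fat and between -2.65 and -2.26 in the other tissues, a difference of 3.49 (SE 0.38, adjusted p = 2.4e-07). The retinol saturase RETSAT was higher by 2.93, the acyl-CoA synthetase ACSL1 by 2.52, the lipolysis inhibitor G0S2 by 2.13, the lipid droplet protein PLIN1 by 1.95 and the triglyceride enzyme DGAT2 by 1.75. Matrix genes followed, with COL1A2 at 2.67, MGP at 2.55, SPARC at 2.38, COL5A1 at 2.34, COL6A1 at 2.33 and COL6A3 at 2.31. XIRP1, held by the contractile apparatus list, was higher by 2.97 (SE 0.40, adjusted p = 1e-05), and PTGDS of the glia and myelin list by 2.01; CD74 of the leukocyte list was higher by 1.33. FGB was lower by -1.32, with an adjusted p of 0.051 without the 3 arrays, and RAMP2, higher by 1.34, had 0.054 without them. Of 55 connective tissue and extracellular matrix genes 15 were called higher and 0 lower, and 21 higher adjusted over the list alone (median 0.48, adjusted p = 2.1e-24). The adipocyte list had 7 of 21 higher, 10 adjusted over the list alone (median 0.45, adjusted p = 2.3e-15). Plasma proteins were lower (median -0.62, adjusted p = 1.7e-14), with 1 of 46 called and 10 lower adjusted over the list alone. Other lower lists lost the call: glycolysis and glycogen (-0.39) had an adjusted p = 0.51 with an estimated correlation, neuronal and synaptic (-0.27) an adjusted p = 0.58 with an estimated correlation, hepatic metabolism (-0.25) an adjusted p = 0.36 with an estimated correlation and acute phase (-0.34) an adjusted p = 0.42 with an estimated correlation. Without the 3 arrays the glycolysis and glycogen list (median -0.53, 4 of 22 lower) passed, at an adjusted p of 0.014 with an estimated correlation. There were 175 called probes, 168 higher and 7 lower, 192 without the 3 arrays, 314 with equal median absolute deviation, 390 with quantile normalisation and 91 without fat replicate 3. Non-overlapping groups were seen for 66 genes (1.03%, against 0.11% by chance).

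**Figure D1:**
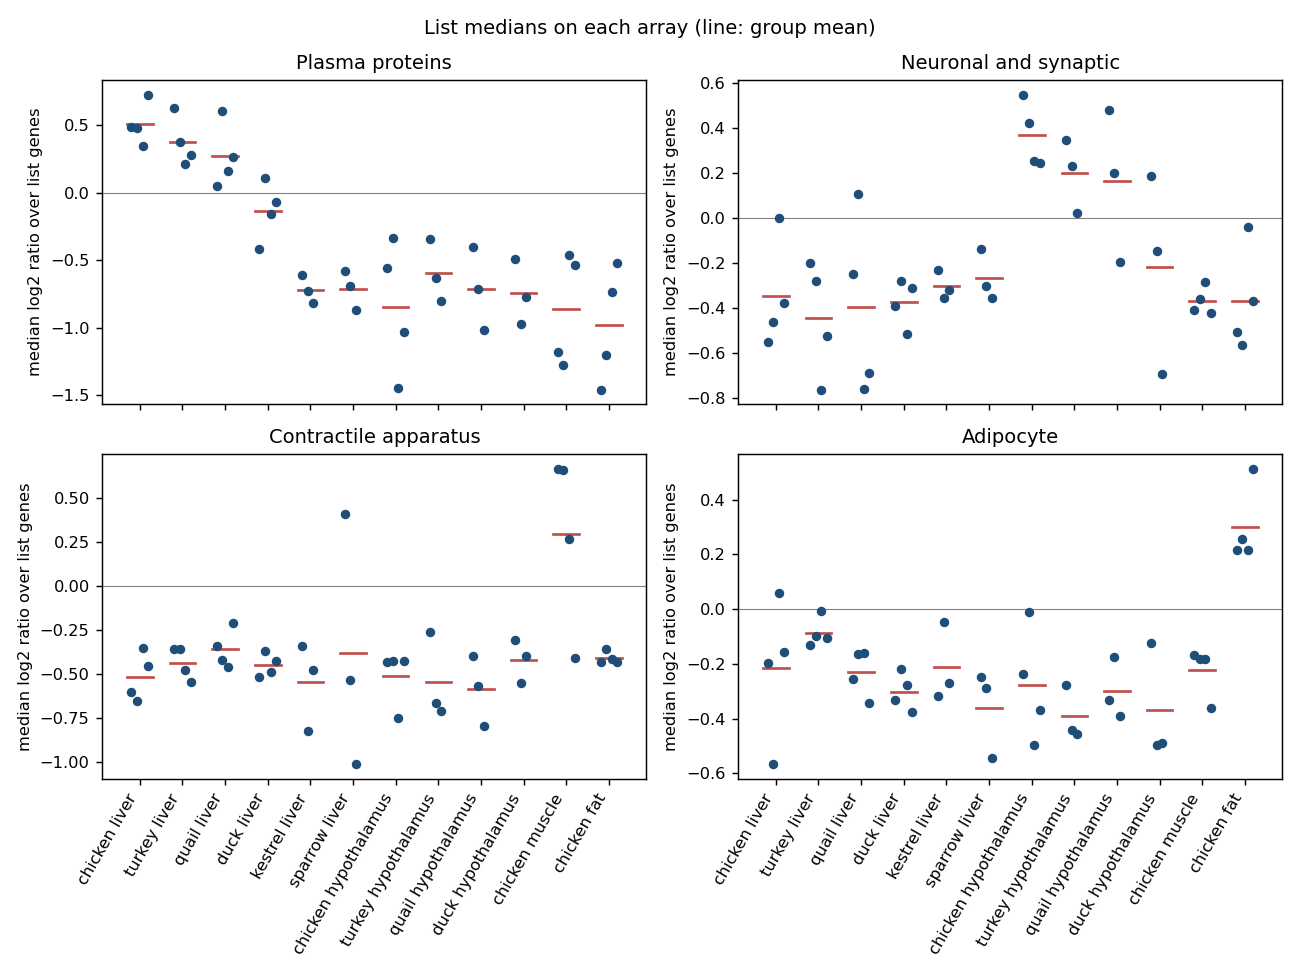
Median log2 ratio over the genes of the plasma protein, neuronal and synaptic, contractile apparatus and adipocyte lists (vertical axes) on each array, by group (horizontal axis), each point an array and each line a group mean. The contractile apparatus list stood at -0.41 on chicken muscle replicate 4 and at 0.41 on sparrow liver replicate 1.

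Within chicken, liver and hypothalamus were also compared directly. PSPH was higher in liver by 3.96 (SE 0.48, adjusted p = 8.8e-07), HSD11B1B by 3.59, ALB by 3.31, LBFABP by 3.30, STEAP3 by 3.29, C3 by 3.27, ORM1 by 2.92 and the vitamin D carrier GC by 2.88. Higher in hypothalamus were STMN3, at -2.55 (SE 0.46, adjusted p = 0.00085), METTL15P1 at -2.46, PTPRN at -2.43, SNCB at -2.19, MBP at -2.16 and DPYSL2, a protein of growing axons, at -1.89. ENO2, at -1.72, lost its call without the 3 arrays (adjusted p = 0.057). Of 46 plasma proteins 17 were higher in liver, and 28 higher and 1 lower adjusted over the list alone (median 1.30, adjusted p = 4.4e-39). The neuronal and synaptic list had 8 of 52 called lower, and 23 adjusted over the list alone (median -0.72, adjusted p = 1.3e-14, or 0.025 with an estimated correlation). In the acute phase list 5 of 12 were higher (median 0.72, adjusted p = 6.9e-12), 5 adjusted over the list alone. In hepatic metabolism 4 of 35 were higher, 8 adjusted over the list alone (median 0.33, adjusted p = 4.5e-07, or 0.033 with an estimated correlation). Glia and myelin genes were lower (median -0.81, 1 of 22 called, 5 adjusted over the list alone) with an adjusted p = 0.2 with an estimated correlation. The count was 254 probes, 187 higher in liver and 67 higher in hypothalamus, and 276 without the 3 arrays. With quantile normalisation it was 526, 316 higher in liver and 210 lower, and with equal median absolute deviation 501. It was 144 without hypothalamus replicate 4 and 154 without liver replicate 1. The tissues did not overlap for 367 genes (5.71%, against 2.86% by chance).

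In turkey the same contrast was led by HSD11B1B, at 3.92 (SE 0.59, adjusted p = 6.9e-05), and by MBP, higher in hypothalamus at -2.96 (SE 0.43, adjusted p = 5.8e-05). C3 was at 1.37 ± 0.37 (SD, n = 4) in turkey liver and at -1.57 ± 0.35 (n = 3) in hypothalamus, a difference of 2.94. The mitochondrial COQ10A (2.99), GC (2.97), LBFABP (2.93), STEAP3 (2.93), the inhibitor chain ITIH2 (2.80) and FGB (2.65) were higher in liver. SNCB (-2.66), the neuronal tubulin TUBB3 (-2.38), ENO2 (-2.07), the lipase maturation factor LMF2 (-1.97) and CALB2 (-1.51) were higher in hypothalamus, and CALB2 lost its call without the 3 arrays. Plasma proteins had 8 of 46 called higher, 20 adjusted over the list alone (median 0.79, adjusted p = 8.2e-28), and acute phase genes 2 of 12, 5 adjusted over the list alone (median 0.73, adjusted p = 9.9e-12). Neuronal and synaptic genes (median -0.57, 4 of 52 lower, 12 adjusted over the list alone) had an adjusted p = 0.099 with an estimated correlation, hepatic metabolism (0.33, 2 of 35 higher, 6 adjusted over the list alone) an adjusted p = 0.058 with an estimated correlation, and glia and myelin (-0.63, 1 of 22, 2 adjusted over the list alone) an adjusted p = 0.36 with an estimated correlation. The count was 105 probes, 78 higher in liver and 27 lower, 109 without the 3 arrays, and 20 and 55 without turkey hypothalamus replicates 2 and 3. With arrays scaled to equal median absolute deviation it was 33. Residuals of same-numbered turkey liver and hypothalamus arrays correlated at 0.268 to 0.624. Those of same-numbered turkey liver and chicken hypothalamus arrays did so at 0.256 to 0.623, so this does not show that the turkey tissues were paired. The count was 94 with replicate as a block. In 345 genes the groups did not overlap (5.37%, against 5.71% by chance).

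Quail liver and hypothalamus differed most in AMBP, a carrier protein of blood, at 4.03 (SE 0.64, adjusted p = 0.00031). PHGDH, the enzyme that opens serine synthesis, was at 2.29 ± 0.72 (SD, n = 4) in quail liver and at -0.98 ± 0.71 (n = 3) in hypothalamus, a difference of 3.27. TM4SF1a (3.76), HSD11B1B (3.44), FGB (3.19), the retinol carrier RBP4A (3.01), HPD (2.76), the purine enzyme ATIC (2.73) and clotting factor F9 (2.40) were higher in liver too. SNCB (-2.28), ENO2 (-2.11), USP34 (-1.82) and MBP (-1.73) were higher in hypothalamus. ADH1C, higher in liver by 1.98, lost its call without the 3 arrays. Of 46 plasma proteins 6 were higher, and 17 adjusted over the list alone (median 0.79, adjusted p = 3.9e-18). Neuronal and synaptic genes (median -0.50, 1 of 52 lower, 12 adjusted over the list alone) had an adjusted p = 0.16 with an estimated correlation, and acute phase genes (0.51, 1 of 12 higher, 3 adjusted over the list alone) an adjusted p = 0.066 with an estimated correlation. Hepatic metabolism (0.38, 3 of 35 higher, 9 higher and 1 lower adjusted over the list alone) had an adjusted p = 0.093 with an estimated correlation, and lipogenesis (0.41, 0 of 17 called) an adjusted p = 0.45 with an estimated correlation. The count was 102 probes, 79 higher and 23 lower, 102 without the 3 arrays and 59 with arrays not centred. It was 29, 26 and 61 without hypothalamus replicates 2 and 3 and liver replicate 3, and 2 with only the compared groups in the fit. No overlap was seen for 487 genes (7.58%, against 5.71% by chance).

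In duck, clones of C3 (3.21, adjusted p = 0.026) and of the protease inhibitor SPINK5 (4.49, adjusted p = 0.0068) were the 2 probes called, both higher in liver and named here after their values were seen. Limma called 0 of 6428 genes, with 347 genes and 903 probes at an unadjusted p under 0.05, near the share of 0.05 that chance alone gives. Plasma proteins were higher in liver (median 0.41, 0 of 46 called, 3 adjusted over the list alone), with an adjusted p = 0.42 with an estimated correlation, and acute phase genes (median 0.31, 0 of 12, 1 adjusted over the list alone) had an adjusted p = 0.36 with an estimated correlation. The neuronal and synaptic list was not called; without the 3 arrays, of which duck hypothalamus replicate 3 is 1, its median was -0.34 (adjusted p = 1.9e-06), with an adjusted p = 0.23 with an estimated correlation. The count was 0 without the 3 arrays. Without duck hypothalamus replicates 2 and 3 it was 1 and 0, and without liver replicates 2, 3 and 4 it was 1, 0 and 0.

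Across all probes, the liver minus hypothalamus difference of chicken correlated with that of turkey at r = 0.514 (rho 0.41, jackknife SE 0.204), with that of quail at 0.246 (rho 0.0899, SE 0.415) and with that of duck at 0.0471 (rho -0.0326, SE 0.343). These are correlations across probes, which are not independent replicates, so no p-value is given. Of the 254 probes called in chicken, 247 had the same sign in turkey (97.2%, against 63.5% of all probes), 244 in quail (96.1%, against 51.1%) and 200 in duck (78.7%, against 47.7%). Called in both species in the same direction were 74 in turkey, 55 in quail and 2 in duck, where independent calls would share 0.884, 0.88 and 0.0202, and 0 were called in opposite directions. The 187 probes higher in chicken liver had a median of 2.30 in chicken, 1.71 in turkey, 1.39 in quail and 0.56 in duck, and since they were picked for their size in chicken their chicken median is raised by that choice. The 67 higher in hypothalamus had medians of -2.11, -1.49, -1.21 and -0.44. Leaving out single arrays moved the correlation between 0.315 and 0.561 for turkey, 0.00254 and 0.457 for quail and -0.126 and 0.262 for duck; the duck value of 0.262 was that without duck hypothalamus replicate 3.

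**Figure D2:**
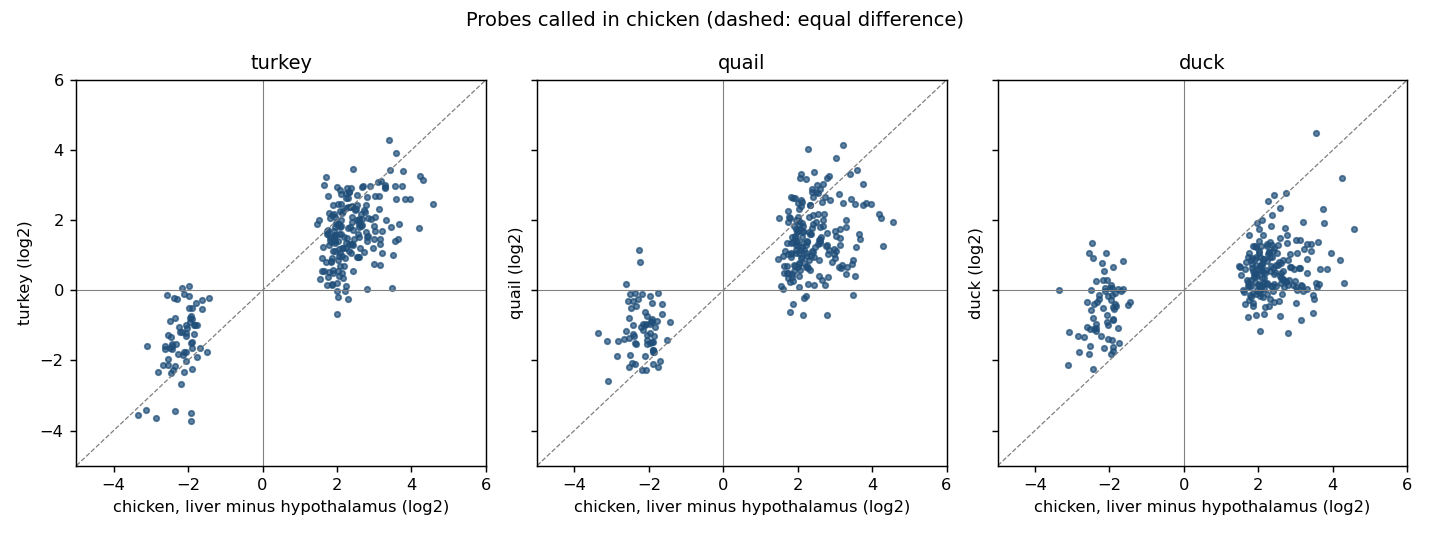
Liver minus hypothalamus log2 difference in turkey, quail and duck (vertical axes) against that in chicken (horizontal axes), each point a probe called in chicken (254 probes). Of these, 247 in turkey, 244 in quail and 200 in duck had the sign seen in chicken.

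Turkey liver differed from chicken liver in few genes, all lower. In the comparisons of species, lower means a lower signal on the chicken clone. Such a signal does not tell expression from a loss of signal on another bird's RNA. The antioxidant enzyme GPX3 was at -1.66 ± 0.70 (SD, n = 4) in turkey and at 0.30 ± 0.57 in chicken liver, a difference of -1.96 (SE 0.39, adjusted p = 0.029). The transporter SLC35E1 was lower by -2.25 (SE 0.45, adjusted p = 0.029) and C4orf48 by -2.09. Clones of CYP20A1 and SNX1 were called as well, named here after their values were seen. Lipogenesis genes were lower (median -0.33, 0 of 17 called, 2 adjusted over the list alone) with an adjusted p = 0.36 with an estimated correlation, and leukocyte genes (-0.20, 0 of 31, 1 adjusted over the list alone) with an adjusted p = 0.52 with an estimated correlation. The count was 9 probes, 0 higher and 9 lower, 31 without the 3 arrays, 30 with quantile normalisation and 0 with arrays not centred. Single arrays moved it: 0, 3, 0 and 1 without chicken liver replicates 1, 2, 3 and 4, and 20, 0 and 3 without turkey liver replicates 2, 3 and 4. Non-overlapping groups were seen for 213 genes (3.31%, against 2.86% by chance).

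In the test per gene, quail liver had 1 gene higher than chicken liver, GPD1, which links glycolysis to lipid synthesis, at 0.98 ± 0.88 (SD, n = 4) against -2.05 ± 1.09 (difference 3.03, SE 0.71, adjusted p = 0.035). The creatine synthesis enzyme GATM was lower, at -1.50 ± 0.91 against 1.14 ± 0.53 (difference -2.64, SE 0.58, adjusted p = 0.024). SLC35E1 (-2.45), ICOSLG (-2.43), the organic anion carrier SLCO1A2 (-2.36), C4orf48 (-2.35), the kinase SNRK (-2.32), ORM1 (-2.25), CYP2D6 (-2.02), B2M of antigen presentation (-1.83, 5 clones) and C3 (-1.63) were lower too. Plasma proteins (median -0.30, 2 of 46 lower, 2 adjusted over the list alone) had an adjusted p = 0.67 with an estimated correlation, and acute phase genes (-0.45, 2 of 12 lower, 3 lower and 1 higher adjusted over the list alone) an adjusted p = 0.45 with an estimated correlation. Clones of PHGDH (3.04, adjusted p = 0.0059) and MAPRE2 (2.39, adjusted p = 0.043) were higher, named here after their values were seen. The count was 76 probes, 6 higher and 70 lower, and 99 without the 3 arrays. It was 39 and 27 without chicken liver replicates 1 and 4 and 37 without quail liver replicate 3, and 2 with arrays scaled to equal median absolute deviation. In 322 genes the groups did not overlap (5.01%, against 2.86% by chance).

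Duck liver gave a lower signal than chicken liver on clones of blood proteins. ALB was at -1.11 ± 0.22 (SD, n = 4) in duck and at 0.82 ± 0.27 in chicken liver, a difference of -1.92 (SE 0.42, adjusted p = 0.013). The oxysterol receptor GPR183 was lower by -3.53 (SE 0.62, adjusted p = 0.0014), ORM1 by -3.18, STEAP3 by -2.91, the glutamate receptor GRIN1 by -2.80, HSD11B1B by -2.67, the adipokine RARRES2 by -2.66, CYP2D6 by -2.61 and GPX3 by -2.41. B2M (-1.69, 5 clones), FGA (-1.88), GC (-2.13), APOH (-1.93), ACAA2 (-1.42), EHHADH (-1.22) and the deiodinase DIO2 (-1.29) were lower too; APOH (-1.93) and EHHADH (-1.22) lost their calls without the 3 arrays, at adjusted p of 0.055 and 0.051. Of 46 plasma proteins 6 were called lower, and 19 adjusted over the list alone (median -0.84, adjusted p = 1.7e-15, or 0.0051 with an estimated correlation). In the acute phase list 2 of 12 were lower, 4 adjusted over the list alone (median -0.84, adjusted p = 1.2e-06, or 0.03 with an estimated correlation). Hepatic metabolism (median -0.19, 2 of 35 lower, 5 adjusted over the list alone) had an adjusted p = 0.29 with an estimated correlation, and its median was 0.04 with arrays centred on ribosomal protein probes, which raised the median of all probes to 0.23 and left the list at -0.19 relative to it. Ribosomal proteins (-0.28, 0 of 44 called) had an adjusted p = 0.77 with an estimated correlation. There were 182 called probes, 2 higher, both without a gene symbol, and 180 lower, 224 without the 3 arrays and 111 with arrays not centred. The count was 104 and 101 without chicken liver replicates 1 and 4, and 84 and 75 without duck liver replicates 3 and 4. No overlap was seen for 401 genes (6.24%, against 2.86% by chance).

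On clones of blood proteins kestrel liver gave a lower signal than chicken liver. C3 was at -1.23 ± 0.32 (SD, n = 3) in kestrel and at 1.57 ± 0.34 (n = 4) in chicken liver, a difference of -2.80 (SE 0.43, adjusted p = 0.00017), and ALB was lower by -2.87 (SE 0.45, adjusted p = 0.00026). HSD11B1B (-3.92), the kinesin binding protein KIF1BP (-3.79), STEAP3 (-3.18), GATM (-2.94), LBFABP (-2.93), SPIA4 (-2.90), ORM1 (-2.88) and APOH (-2.79) were lower, as were HPD (-2.54), the iron carrier TF (-1.82), the desaturase FADS1 (-1.51) and B2M (-1.93). KLHDC10 (1.40) and the calcium sensor CABP1 (1.23) were the genes called higher, of which CABP1 lost its call without the 3 arrays (adjusted p = 0.05), and clones of TMEM260, STK10 and C11orf54 were among the higher probes, named here after their values were seen. Plasma proteins had 15 of 46 lower, 27 adjusted over the list alone (median -1.34, adjusted p = 1.5e-26), and acute phase genes 5 of 12, 8 adjusted over the list alone (median -1.38, adjusted p = 1.4e-11). Hepatic metabolism (-0.45, 3 of 35 lower, 6 adjusted over the list alone) had an adjusted p = 0.2 with an estimated correlation, leukocyte genes (-0.32, 1 of 31, 1 adjusted over the list alone) an adjusted p = 0.56 with an estimated correlation and lipogenesis (-0.35, 1 of 17, 3 adjusted over the list alone) an adjusted p = 0.52 with an estimated correlation. The count was 244 probes, 5 higher and 239 lower, and 275 without the 3 arrays. It was 153 and 131 without chicken liver replicates 3 and 4, and 140 and 78 without kestrel liver replicates 2 and 3. Non-overlapping groups were seen for 538 genes (8.37%, against 5.71% by chance).

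Clones of blood proteins gave a lower signal in sparrow liver than in chicken liver. LBFABP was at -2.81 ± 0.47 (SD, n = 3) in sparrow and at 0.92 ± 0.92 (n = 4) in chicken liver, a difference of -3.73 (SE 0.58, adjusted p = 0.00018), and HSD11B1B was lower by -3.78 (SE 0.59, adjusted p = 0.00018). PSPH (-3.25), ORM1 (-3.14), FGB (-2.85), C3 (-2.81), AMBP (-2.76), ADH1C (-2.62), the lectin MBL2 (-2.27) and the citrate lyase ACLY (-1.09) were lower. EHHADH was lower by -1.64, from clones at -3.28 and 0. Of 46 plasma proteins 11 were lower, and 32 lower and 1 higher adjusted over the list alone (median -1.25, adjusted p = 6e-34). The acute phase list had 6 of 12 lower, 7 adjusted over the list alone (median -1.57, adjusted p = 4.2e-17), and hepatic metabolism 1 of 35, 9 adjusted over the list alone (median -0.67, adjusted p = 1.1e-08); without the 3 arrays the latter had a median of -0.86 and an adjusted p = 0.088 with an estimated correlation. Lipogenesis (-0.47, 1 of 17 lower, 6 adjusted over the list alone) had an adjusted p = 0.066 with an estimated correlation. Contractile apparatus genes were higher (median 0.56, 0 of 43 called, 1 adjusted over the list alone) with an adjusted p = 0.13 with an estimated correlation, and glycolysis and glycogen genes (0.56, 0 of 22) with an adjusted p = 0.74 with an estimated correlation; without the 3 arrays, sparrow liver replicate 1 among them, their medians were 0.22 (adjusted p = 0.3) and -0.16 (adjusted p = 0.84). The count was 156 probes, 0 higher and 156 lower, 231 without the 3 arrays, 243 with quantile normalisation and 67 without sparrow liver replicate 3. In 424 genes the groups did not overlap (6.6%, against 5.71% by chance).

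**Figure D3:**
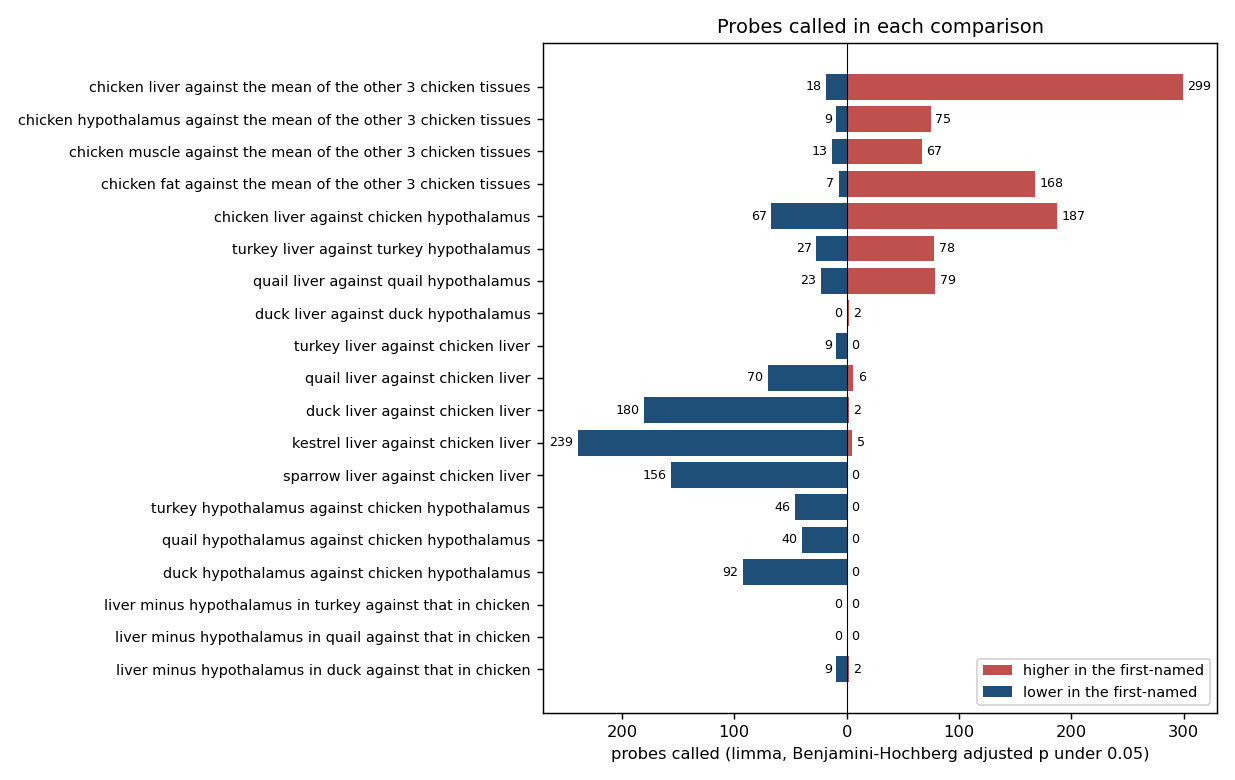
Number of probes called higher and lower (horizontal axis) in each comparison (vertical axis) at an adjusted p under the threshold. Liver of the other species against chicken liver gave 9, 70, 180, 239 and 156 lower probes in turkey, quail, duck, kestrel and sparrow.

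Hypothalamus of the other species was lower than that of chicken in a small set of genes, of which ARIH1, a ubiquitin ligase, was called in every species. It was at 0.80 ± 0.31 (SD, n = 4) in chicken and at -1.52 ± 0.50 in turkey, -1.71 ± 0.48 in quail and -2.27 ± 0.93 in duck (n = 3 each), with differences of -2.32, -2.51 and -3.07 (SE 0.46 each). CYP2D6 was lower in turkey (-2.44), quail (-2.67) and duck (-2.27). In turkey the histone H3F3C (-2.93), SNRK (-2.83), SMIM15 (-2.60), the kinase CAMKK2 (-2.55), ICOSLG (-2.38), PWP1 (-2.26) and OARD1 (-2.10) were lower too. Quail had PPIL4, a cyclophilin, lower by -2.82 (SE 0.58, adjusted p = 0.045). In duck the adaptor AP1M1 was lower by -4.03 (SE 0.61, adjusted p = 0.00026), SNRK by -3.61, METTL15P1 by -2.62, SLC35E1 by -2.61, MRTO4 by -2.58, PPIL4 by -2.51, GFAP by -2.48 and the nucleotidase NT5M by -2.45; without the 3 arrays, which left 2 duck hypothalami, METTL15P1 (-2.33), MRTO4 (-2.27), PPIL4 (-1.85) and GFAP (-2.17) lost their calls. The neuronal and synaptic list was lower in turkey (median -0.17, 0 of 52 called), with an adjusted p = 0.71 with an estimated correlation and medians of 0.06 with arrays not centred and 0.07 with arrays centred on ribosomal protein probes, where all probes had medians of 0.26 and 0.27, so that relative to all probes it stayed at -0.20. In quail it was lower (-0.20, 0 of 52; 0.03 with arrays not centred, where all probes had 0.30, so that it stayed at -0.27 relative to them), with an adjusted p = 0.7 with an estimated correlation, and in duck (-0.60, 0 of 52, 8 adjusted over the list alone) with an adjusted p = 0.13 with an estimated correlation. Glia and myelin genes in quail (-0.26, 0 of 22, 2 adjusted over the list alone) had an adjusted p = 0.62 with an estimated correlation, and in duck (-0.69, 1 of 22, 2 adjusted over the list alone) an adjusted p = 0.37 with an estimated correlation. Without the 3 arrays the duck medians of these lists were -0.29 and -0.24. Ribosomal proteins in turkey (-0.29, 0 of 44) had an adjusted p = 0.77 with an estimated correlation, as in duck (-0.35, 0 of 44, 2 adjusted over the list alone, and 0.02 with arrays centred on ribosomal protein probes, which holds their own median near 0), where the adjusted p = 0.77 with an estimated correlation. Erythrocyte genes in quail were higher (0.59, 0 of 10) with an adjusted p = 0.17 with an estimated correlation.

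Called probes in hypothalamus numbered 46 in turkey, 40 in quail and 92 in duck, with 0 higher in each. In limma 578, 703 and 1579 probes had an unadjusted p under 0.05. Chance alone would put a share of 0.05 of all probes there, which is more than in turkey and quail. Without the 3 arrays the counts were 95, 77 and 36, and with arrays not centred 2, 3 and 59. The turkey count was 2 and 1 without chicken hypothalamus replicates 1 and 2, and 81, 0 and 1 without turkey hypothalamus replicates 1, 2 and 3. For quail it was 2, 5 and 26 without chicken hypothalamus replicates 1, 2 and 3, and 2 and 1 without quail hypothalamus replicates 2 and 3. For duck it was 27 and 45 without chicken hypothalamus replicates 1 and 2, and 272, 16 and 15 without duck hypothalamus replicates 1, 2 and 3. No overlap was seen for 260 genes in turkey (4.04%), 367 in quail (5.71%) and 424 in duck (6.6%), against 5.71% by chance in each. The chicken hypothalami came from a lean line, so line goes with species here.

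The liver minus hypothalamus difference in signal differed between species for STEAP3 and METTL15P1. A loss of signal of the chicken clone on another bird's RNA can also flatten this difference, and that was not tested for these genes. Chicken liver came from broilers at 6 weeks and chicken hypothalamus from a lean line at 9 weeks. Line and age therefore go with the chicken difference. STEAP3 was at 1.08 ± 0.36 (SD, n = 4) in chicken liver and at -2.21 ± 0.24 in chicken hypothalamus, while in duck it was at -1.83 ± 0.34 (n = 4) and -1.86 ± 0.85 (n = 3). Its liver minus hypothalamus difference was lower by -3.26 in duck (SE 0.51, adjusted p = 0.00086) and by -2.84 in quail (SE 0.51, adjusted p = 0.012) than in chicken. METTL15P1 was at -1.14 ± 1.01 in chicken liver and at 1.33 ± 0.73 in chicken hypothalamus, but at 0.05 ± 0.57 and -1.30 ± 0.83 in duck. Its sign was thus reversed in duck and not only flattened, though the difference within duck was not called. Between duck and chicken it differed by 3.81 (SE 0.69, adjusted p = 0.0074). Without the 3 arrays it differed by 3.52 (SE 0.75) and lost its call. A clone of ALB differed by -3.34 in duck, named here after its value was seen. Plasma proteins had a smaller tissue difference in duck than in chicken (median -0.91, adjusted p = 1.6e-12, or 0.018 with an estimated correlation). Of these genes 0 of 46 were called, and 8 were lower adjusted over the list alone. In quail (-0.34, 0 of 46) plasma proteins had an adjusted p = 0.66 with an estimated correlation. Other lists in duck lost the call: glia and myelin (0.89, 0 of 22) had an adjusted p = 0.38 with an estimated correlation, neuronal and synaptic (0.46, 0 of 52) an adjusted p = 0.38 with an estimated correlation, acute phase (-0.31, 0 of 12, 3 adjusted over the list alone) an adjusted p = 0.36 with an estimated correlation and hepatic metabolism (-0.34, 0 of 35) an adjusted p = 0.49 with an estimated correlation. Glia and myelin genes in quail (0.51, 0 of 22) had an adjusted p = 0.55 with an estimated correlation. Limma called 0 probes in turkey (287 at an unadjusted p under 0.05), 0 in quail (877) and 11 in duck, 2 higher and 9 lower. A share of 0.05 of all probes, as chance alone gives, is more than the 287 and 877. Without the 3 arrays the counts were 0, 0 and 2, and the duck count was 3 with arrays not centred and 42 with quantile normalisation. The turkey count was 1 without turkey hypothalamus replicate 2. In duck it was 6, 7 and 6 without chicken hypothalamus replicates 3 and 4 and chicken liver replicate 1, and 7, 2 and 6 without duck hypothalamus replicates 1 and 3 and duck liver replicate 4.

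Lists of 8 further gene groups passed the threshold in no comparison. Their lowest adjusted p were 0.22 for cholesterol synthesis (15 genes), 0.069 for fatty acid oxidation and ketogenesis (20 genes), 0.1 for hypothalamic neuropeptides and regulators (9 genes), 0.071 for endothelial genes (22), 0.083 for oxidative phosphorylation (45), 0.34 for the proteasome (34), 0.16 for the circadian clock (10) and 0.14 for heat shock and immediate early genes (23). Of the egg yolk precursors 0 genes were measured. Over all 399 tests of 21 lists in 19 comparisons, 83 passed with the preset correlation and 26 with an estimated correlation.

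On average, log ratios spread more widely on the arrays of every other species than on those of chicken, but no test could pass with these numbers of arrays. The mean SD over probes was 0.699 ± 0.122 (SD, n = 4) in chicken liver and 0.874 in turkey, 0.910 in quail, 0.790 in duck, 0.934 in kestrel and 0.885 in sparrow liver. In hypothalamus it was 0.704 ± 0.147 (n = 4) in chicken and 0.810, 0.846 and 0.915 in turkey, quail and duck. The lowest p was 0.0571, in quail liver (exact permutation test, two-sided), and adjusted over the 8 comparisons the values were 0.457 to 0.514. The smallest p that 4 against 4 arrays allow is 0.0286, and 3 against 4 allow 0.0571 (exact permutation test), so that those with 3 arrays could not pass. Repeat spots of 1 clone, 94 per array, had an SD of 0.592 to 0.861 on the chicken livers. It was 0.704 to 1.24 in turkey, 0.737 to 1.04 in quail and 0.666 to 1.06 in duck liver. In kestrel it was 0.622 to 1.29 and in sparrow 0.432 to 1.21. A wider spread over probes can therefore not be told apart from a wider scatter of spots.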

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

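The tests of swapped, mixed or wrong labels, also by species, and of compressed log ratios were chosen only after the result was seen; the tests of a loss of signal in both tissues and of other splits were set before. Dixon's test was run on 84 combinations of a group of 4 arrays and a measure and marked 6 of them, where chance marks about 1 in 20.

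On chicken muscle replicate 4 the glycolysis and glycogen list lay at -0.87 and the other muscle arrays at 0.80 to 0.88, a gap of 0.954 of the group's range, and its erythrocyte list lay at 0.26 against -0.28 to -0.24, a gap of 0.916. The erythrocyte list of chicken liver replicate 3 lay at 0.24 against -0.32 to -0.23 (gap 0.855). The contractile apparatus list of chicken hypothalamus replicate 3 lay at -0.75 against -0.43 to -0.42 (gap 0.974). Chicken fat replicate 3 had a mean correlation of 0.0877 with its group, against 0.272 to 0.285 for the others (gap 0.932). The median log2 ratio of quail liver replicate 2 was -0.36 and those of the other quail livers -0.03 to -0.01 (gap 0.934).

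Sparrow liver replicate 1 carried contractile transcripts: TNNT3 was at 1.58, MYL1 at 1.97 and MYH1B at 1.72. TNNI2 was at 1.22 and ACTA1 at 0.45. The troponin TNNC2 went the other way, at -0.39, against 1.30 to 1.72 on the other sparrow livers. On muscle replicates 1 to 3 it was at 0.01 to 1.05. Sparrow muscle mixed into a sparrow liver sample is argued against by 62 probes called lower in the hypothalamus of at least 2 of the 3 other species with the arrays in doubt left out: their median was 0.10 on this array, between -0.66 and 0.75 on the chicken arrays other than muscle replicate 4, and -1.84 and -1.24 on the other sparrow livers. After the mean over groups and the first residual component were removed, this array correlated with chicken muscle replicates 1 to 3 at a mean r of 0.427, where these correlated among themselves at 0.305, which is consistent with a chicken muscle sample under a sparrow liver label. Chicken muscle with a share of sparrow liver cannot be told apart from that, since its plasma protein median of -0.58 lay above the lower of the other sparrow livers, -0.87, and muscle replicates 1 to 3 lay at -1.28 to -0.46.

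Chicken muscle replicate 4 lacked contractile transcripts. A chicken hypothalamus sample under its label is argued against by its neuronal and synaptic median of -0.42, where the lowest chicken hypothalamus lay at 0.24. On the same 62 probes its median was -1.92, where the arrays of other species except sparrow liver replicate 1 lay between -2.80 and -1.17, which is consistent with RNA of another species under a chicken label; the arrays closest to it were duck hypothalamus replicate 2 (r = 0.682) and duck liver replicates 3 (0.549) and 1 (0.533). A swap with sparrow liver replicate 1 stays open. After the mean over groups and the first residual component were removed, its mean r with sparrow liver replicates 2 and 3 was 0.00306. As these correlated with each other at -0.00684, the test could not decide. The correlations with duck arrays were taken without that removal, where arrays of different groups had a median r of 0.263. They cannot be set against the sparrow values. No biological explanation was tested for either array.

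Probes called lower in turkey, quail and duck liver were mostly lower in the hypothalami of these species too. A loss of signal of the chicken probe on RNA of another species may underlie this, since it would act alike in both tissues: the median hypothalamus difference of these probes was -1.62 in turkey (8 of 9 below 0) and -1.14 in quail (56 of 70), and in duck -0.81 with an upper quartile of 0.05 (132 of 180, 73.3%, against 47.0% of all probes), where it stays open because part of the probes were not lower. Compression of the log ratios toward 0 on arrays of other species would leave these probes between 0 and their chicken values. All of them lay below 0 in liver of the other species (9 of 9, 70 of 70 and 180 of 180). Their medians were -2.24 in turkey, -2.07 in quail and -1.87 in duck liver, against -0.07, 0.16 and 0.36 in chicken liver. Compression therefore does not account for these calls. Since the probes were picked as lower on the same liver arrays, they do not test compression over whole arrays. Sequence of the clones in these birds is not in the data, and a true difference in expression between the species stays open as untested. Kestrel and sparrow had no hypothalamus arrays, so the loss of signal could not be checked in them.

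The liver minus hypothalamus difference differed between duck and chicken for 11 probes, among them METTL15P1 (3.81) and STEAP3 (-3.26), and for STEAP3 between quail and chicken (-2.84) in the test per gene. The plasma protein list differed by a median of -0.91 between duck and chicken. Of 100 splits of the duck and chicken arrays 1, the real one, gave as many as 11 probes and the highest other gave 6. The other splits exchange duck and chicken arrays within a tissue, which puts the species differences into the spread within groups. They therefore cannot exclude chance for that count. With residual arrays reshuffled among the groups, 0 of 100 draws gave as many, and the highest gave 1. Of 100 splits for quail, and of 100 for turkey, every one gave at least the real count of 0, as any split must, so these splits say nothing about chance; the highest others were 1 and 736, and the split with 736 points to a structure of the samples. Without duck hypothalamus replicate 3 the duck count was 2.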

How the results depend on the processing

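Averaging the spots of a clone, leaving out 3 arrays in doubt, centring print blocks and the residual component as a covariate were chosen after seeing the data, and centring itself changed from alternative to choice then. A value is given below where a count of called probes moved by more than 1.5 times. The cause was not tested except where the construction shows it. Comparisons are named by tissue: chicken tissues against the mean of the others, liver against hypothalamus within a species, other species against chicken within a tissue, and interactions for the difference of tissue differences between a species and chicken. No named gene reversed its direction, and where a change of centring turned the sign of 4 list medians it moved all probes alike: relative to all probes neuronal and synaptic genes stayed at -0.20 in turkey and -0.27 in quail hypothalamus, hepatic metabolism at -0.19 in duck liver and ribosomal proteins at -0.40 in duck hypothalamus. The planned filter for probes with a value on all arrays and the share of probes with a value were not run, since no cell was empty.

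With 1 test per gene, which tests fewer items by construction, counts were 128 for chicken liver, 31 for hypothalamus, 38 for muscle and 80 for fat; 97, 44, 36 and 0 for liver against hypothalamus in chicken, turkey, quail and duck; 3, 33, 49, 78 and 51 for turkey, quail, duck, kestrel and sparrow livers; 9, 3 and 21 for turkey, quail and duck hypothalami; and 1 and 2 for the quail and duck interactions.

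With arrays not centred, counts were 43 for chicken hypothalamus, 59 for quail liver against hypothalamus, 0 and 111 for turkey and duck livers, 2, 3 and 59 for turkey, quail and duck hypothalami and 3 for the duck interaction. Without centring, the median difference of all probes was -0.24 in chicken hypothalamus, 0.21 in chicken liver against hypothalamus and -0.47 in the quail interaction, the largest of the 19. With arrays centred on ribosomal protein probes, counts were 25, 91 and 152 for turkey, duck and kestrel livers and 16 and 32 for turkey and duck hypothalami; the median of all probes was 0.42 in duck hypothalamus. With equal median absolute deviation they were 247 and 314 for chicken hypothalamus and fat, 501, 33, 17 and 0 for liver against hypothalamus in chicken, turkey, quail and duck, 0, 2 and 119 for turkey, quail and kestrel livers and 2 and 21 for turkey and duck hypothalami. With quantile normalisation they were 260, 175 and 390 for chicken hypothalamus, muscle and fat, 526 for chicken liver against hypothalamus, 30 and 243 for turkey and sparrow livers and 4 and 42 for the quail and duck interactions. With print blocks centred they were 20 and 275 for turkey and duck livers and 0 for duck liver against hypothalamus. With no averaging of spots the turkey liver count was 28.

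With array weights, counts were 679, 542, 240 and 381 for chicken liver, hypothalamus, muscle and fat, 899, 174, 720 and 1267 for liver against hypothalamus in chicken, turkey, quail and duck, 40 and 696 for turkey and duck livers, 171, 1491 and 2670 for turkey, quail and duck hypothalami and 91 and 994 for the quail and duck interactions; quail hypothalamus replicate 2 had a weight of 60.6, the others 0.315 to 3.31, and the weight estimation stopped early with a warning, so these counts rest on unconverged weights. With the first residual component as a covariate they were 478, 395, 341 and 391 for the chicken tissues, 582, 261, 255 and 49 for liver against hypothalamus in chicken, turkey, quail and duck, 127, 447, 558, 621 and 364 for turkey, quail, duck, kestrel and sparrow livers, 171, 143 and 426 for turkey, quail and duck hypothalami and 1, 18 and 92 for the turkey, quail and duck interactions; since that component was taken from the residuals of the same fit, these counts are too favourable by construction. With only the compared groups in the fit they were 127 and 131 for chicken hypothalamus and muscle, 2 and 6 for quail and duck liver against hypothalamus, 26, 38 and 430 for turkey, quail and duck livers and 73, 0 and 47 for turkey, quail and duck hypothalami. With a replicate block they were 32 for turkey liver and 84, 71 and 140 for turkey, quail and duck hypothalami. Without the 3 arrays in doubt they were 195 for chicken muscle, 0 for duck liver against hypothalamus, 31 for turkey liver, 95, 77 and 36 for turkey, quail and duck hypothalami and 2 for the duck interaction.

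Leaving out 1 array at a time, counts ran from 225 to 330 for chicken liver, 30 to 97 for hypothalamus, 0 to 177 for muscle and 91 to 210 for fat. For liver against hypothalamus they ran from 144 to 288 in chicken, 20 to 87 in turkey, 26 to 107 in quail and 0 to 2 in duck. For livers they ran from 0 to 20 in turkey, 27 to 69 in quail, 75 to 159 in duck, 78 to 240 in kestrel and 67 to 215 in sparrow, and for hypothalami from 0 to 81 in turkey, 1 to 36 in quail and 15 to 272 in duck. For the interactions they ran from 0 to 1 in turkey, 0 to 0 in quail and 2 to 13 in duck. The lowest count for muscle came without replicate 1 or 2 (0 each), and the highest without replicate 4 (177). The correlations with chicken ran from 0.315 to 0.561 in turkey, 0.00254 to 0.457 in quail and -0.126 to 0.262 in duck, within their jackknife errors; the duck value changed sign with array weights (-0.0251) and with print blocks centred (-0.0246), also within its error. The differences in SD per array ran from 0.105 to 0.254, 0.172 to 0.277, 0.062 to 0.152, 0.135 to 0.393 and 0.076 to 0.377 for turkey, quail, duck, kestrel and sparrow livers and from 0.00573 to 0.174, 0.00567 to 0.278 and 0.0734 to 0.347 for turkey, quail and duck hypothalami.

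List tests past the threshold numbered 83, 26 with the correlation estimated from residuals and 76 to 89 leaving out 1 array. Of 242 pairs of a named gene and a comparison, none reversed; 61 lost the call with arrays not centred, 86 with equal median absolute deviation, 52 with only the compared groups in the fit, 25 of 169 with ribosomal protein centring, 20 with print blocks centred, 14 with a replicate block, 4 with array weights, 3 with quantile normalisation, 3 with robust eBayes and 15 without the 3 arrays, as did 576 of 2442 leaving out 1 array. The share of called probes that were higher moved by more than 10 percentage points for chicken hypothalamus (89.3% to 65.1% with arrays not centred and 78.9% with equal median absolute deviation), chicken liver against hypothalamus (73.6% to 86.0% not centred and 60.1% quantile normalised), chicken liver (94.3% to 83.5% quantile normalised), muscle (83.8% to 72.0% quantile normalised), turkey liver against hypothalamus (74.3% to 45.8% with ribosomal protein centring and 60.6% with equal median absolute deviation) and the duck interaction (18.2% to 33.3% not centred and 7.69% with print blocks centred). Signal over background is unknown, so what depth limits could not be tested.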

Other observations

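The comparison of other splits was set before the results were seen; how many lower probes the species share was looked at after them. Genes lower in both tissues of a species than in chicken were ARIH1 and CYP2D6 in quail and C4orf48, CAMKK2, CLSTN3, CYP2D6, FAM13B, MRTO4, NT5M, OARD1, SLC35E1 and SNRK in duck. At the level of probes, 2 were called lower in both tissues of turkey, 11 of quail and 37 of duck, where independent calls would share 0.0223, 0.151 and 0.893.

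Probes lower than in chicken liver were shared between species: 112 between kestrel and sparrow, 91 between duck and kestrel, 62 between duck and sparrow, 48 between quail and duck, 33 between quail and kestrel and 16 between quail and sparrow. Turkey shared 7 with quail, 8 with duck, 2 with kestrel and 1 with sparrow. These contrasts use the same chicken liver arrays, which alone can make probes shared. With the 4 chicken livers split so that kestrel and sparrow were compared with different ones, they shared 27 to 36, and duck shared 6 to 15 with kestrel and 9 to 20 with sparrow. The lists themselves shrank in these splits, where each side had 2 chicken livers, to a median of 0.5 lower probes in turkey, 9 in quail, 38.5 in duck, 74 in kestrel and 74.5 in sparrow, so the smaller shared counts do not measure the effect of shared controls alone. In the other pairs quail shared 0 to 3 with duck, 0 to 5 with kestrel and 0 to 4 with sparrow, and turkey 0 with quail, kestrel and sparrow and 0 to 1 with duck. In simulated groups with no change the median shared count was 0 for each of these pairs, but single draws reached 560 for duck and kestrel, 535 for turkey and kestrel and 409 for turkey and duck.

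Other splits of the same arrays were counted for each comparison. For chicken liver 1 of 100 splits gave as many as 317 probes, the real one, and the highest other gave 90. For hypothalamus 4 of 100 gave as many as 84 (highest other 114). For muscle 3 of 100 gave as many as 80 (113) and for fat 2 of 100 as many as 175 (309). The other splits mix tissues, which puts tissue differences into the spread within groups, so by themselves they cannot exclude chance. With residual arrays reshuffled among the groups, 1, 2, 1 and 2 of 100 draws gave as many for liver, hypothalamus, muscle and fat. The muscle count was lost without single muscle arrays, as given above. For liver against hypothalamus 1 of 35 splits, the real one, gave as many in chicken (254, highest other 39), turkey (105, highest other 22, and 8 among splits that part every pair) and duck (2, highest other 0). These splits mix the tissues as well and carry the same limit. In the reshuffled draws 1 of 100 gave as many in chicken and 0 of 100 in turkey. The duck count of 2 was lost without the 3 arrays in doubt and without single duck arrays, so no conclusion is drawn from it. In quail 4 of 35 gave as many as 102, so chance cannot be excluded; the highest other gave 2786, several times the real count, and parted replicates 1 and 2 of both tissues from the other quail arrays, which points to a structure of the samples. For liver of other species against chicken the real split alone, 1 of 35, gave as many in each species. The counts were 9 in turkey (highest other 1), 76 in quail (0) and 182 in duck (1). They were 244 in kestrel (43) and 156 in sparrow (44). The other splits mix the species, which puts species differences into the spread within groups, so by themselves they cannot exclude chance. In the reshuffled draws 3 of 100 gave as many in turkey, 1 each in quail and duck, and 0 each in kestrel and sparrow. For hypothalamus 1 of 35, the real split, gave as many in turkey (46, highest other 0) and quail (40, highest other 3). These splits mix species too, and 1 and 0 of 100 reshuffled draws gave as many. The probes at an unadjusted p under 0.05 in limma, 578 and 703, were fewer than chance alone gives, so chance is not excluded there. In duck 2 of 35 gave as many as 92, so chance cannot be excluded. The highest other gave 1191 and put chicken replicate 3 with duck replicates 2 and 3, so a structure of the samples shows again.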
